A study of Mus musculus with 15 samples.

How the data were processed

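The samples were 15 RNA sequencing libraries of sorted alveolar macrophages in 5 groups of 3, each library from a pool of 2 to 3 mice and about 50000 cells per the labels. The authors deposited raw counts per gene, with 1 column per library. Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts of the Subread package, without versions, parameters or strand setting, so counts of overlapping and antisense genes are uncertain. The genome build was not given in the sources used here. The count table held 40780 rows, of which 270 repeated a gene (160 genes) with the same counts under another annotation, and these were removed, leaving 40510 genes. Of them 25100 had at least 1 count. Genes were named by the deposited Ensembl identifiers and symbols, and coordinates of Cybb were read by symbol from GENCODE M21 on GRCm38.

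Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 13284 genes for testing and at least 99.9% of the counts in each library. TMM factors scaled the library totals, and gene levels are TMM-scaled CPM. Summed CPM of marker genes and the levels of Xist, Eif2s3y and Ddx3y are per library total without TMM scaling. A robust quasi-likelihood fit held all 15 libraries with 1 coefficient per group, leaving 10 residual degrees of freedom. Contrasts gave 7 comparisons: knockout against wild-type CD11b-low cells at 12 and at 4 weeks, CD11b-high against CD11b-low knockout cells, CD11b-high knockout against CD11b-low wild-type cells, 12 against 4 weeks in each genotype, and the interaction of genotype and age. Tests were two-sided and p-values were adjusted by Benjamini and Hochberg at 0.05. In tests on simulated data with a spread per gene shared by all groups, 100 genes were changed by each known fold. Real groups differed in spread, so the rates are approximate. Changes of 4-fold were recovered in 68% of genes for knockout against wild-type cells at 12 weeks (13020 genes tested in this step), 65% at 4 weeks (13041), 70% for CD11b-high against CD11b-low cells (13039) and 74% for CD11b-high knockout against wild-type cells (13028). They were recovered in 74% with age in knockout (13000), 66% in wild-type cells (12998) and 28% in the interaction (13005). Changes of 2-fold were recovered in 13, 5, 13, 20, 11, 18 and 4% in that order, and 1 to 5 unchanged genes were called. For the 12-week genotype comparison DESeq2 recovered 35% at 2-fold and 74% at 4-fold with 29 unchanged genes called, and limma voom 13% and 67% with 3.

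Gene lists were written from textbook knowledge, and these lists, the comparisons, the rule for naming genes and the alternatives were fixed before the data were examined. The 33 lists cover alveolar macrophage identity, monocyte-derived and lipid-associated macrophages, lipid uptake and storage, cholesterol biosynthesis, cholesterol efflux and LXR targets, fatty acid oxidation, glycolysis and hypoxia, oxidative phosphorylation, cytokines and chemokines, NF-kappaB targets, interferon response, MHC class II presentation, matrix remodelling, alternative activation, NRF2 targets, NADPH oxidase subunits, antioxidant enzymes, lysosome, cell cycle, apoptotic cell clearance, pattern recognition, the unfolded protein response, immediate early and handling stress genes, TGF-beta receptor and SMAD targets, and markers of neutrophils, eosinophils, T and NK cells, B and plasma cells, dendritic cells, lung epithelium, erythroid cells and sex. Lists with at least 5 tested genes (32 of 33) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over lists. They were repeated with an estimated correlation and with fry. A simulated list of 20 genes raised together was called by all 3 in each of the 7 comparisons, and of 20 random lists none was called apart from 1 by fry at 4 weeks.

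Named genes were Cybb and the sort markers Itgam, Itgax, Siglecf and Ptprc. For the genotype comparisons and for CD11b-high against CD11b-low cells, the 10 largest rises and 10 largest falls were named, and 5 of each for the others. They had to pass the threshold, have a mean of at least 10 CPM in the higher group, no overlap between the libraries of the groups compared, and a symbol that is neither predicted nor that of a pseudogene. For 3 libraries against 3, chance gives no overlap to 10% of genes. For the interaction, separation was judged on the 12-week libraries and the CPM minimum on the highest of the 4 groups. Each described list gave up to 4 members past the threshold, or 2 by level where none passed. Some genes that met these rules are not reported here. A list was described when it passed or had at least 3 genes past the threshold, many by counts or adjusted p alone. A group with 0 counts in all libraries was set to a floor of 3 counts in each library for an at-least fold. Cybb in knockout against wild-type libraries was also tested by exact permutation over 5005 regroupings, and over 400 within each age in CD11b-low libraries.

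Replicate numbers in the sample titles were checked for pairing by correlating deviations from group means across genes. CD11b-high and CD11b-low knockout libraries of one number correlated at 0.429, 0.353 and 0.113, each library best with its own number, but the main test takes them as independent. In the other comparisons numbers did not pair.

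Alternatives changed 1 choice at a time: RLE size factors in place of TMM, no filter on low counts, DESeq2 1.42.0 on all genes with its own filter, which replaces the filter as well as the test, limma voom with library weights, only the groups compared in the fit, the replicate number as a block, leaving out each library in turn, and, for lists, the estimated correlation and fry. DESeq2 on the genes kept by filterByExpr was added after the results were seen. Splits of the libraries into other groups of the same sizes were refitted. Shared wild-type controls were examined with 20 simulations of unchanged, independent groups. Shared 50-mers between transcripts were counted with numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9. No library was left out of the fit.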

Results

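RNA was sequenced from alveolar macrophages, the resident phagocytes of the airspaces, that were washed from the lungs of untreated mice by bronchoalveolar lavage. The mice were wild-type C57BL/6 animals or animals of the same background without a working Cybb gene, a model of chronic granulomatous disease. Cybb encodes the catalytic subunit (NOX2, gp91phox) of the phagocyte NADPH oxidase, the enzyme complex that makes superoxide. Cells were sorted as CD45+ Ly6G- SiglecF+ CD11c+ and split by their surface CD11b, the integrin chain encoded by Itgam. There were 5 groups of 3 independent replicates each: CD11b-low cells of knockout and of wild-type mice at 4 weeks, CD11b-low cells of knockout and of wild-type mice at 12 weeks, and CD11b-high cells of knockout mice at 12 weeks. No CD11b-high group from wild-type mice was among the samples. Each replicate pooled 2 to 3 mice and about 50000 cells. The 15 libraries held 22856331 to 36458893 counts (median 32415469), and 15889 to 17973 genes had at least 1 count. Levels are library-scaled counts (CPM, scaled by TMM), given as mean ± SD over n = 3 libraries per group. Fold changes and adjusted p-values of genes come from two-sided quasi-likelihood tests in edgeR over 13284 genes.

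The targeted gene was checked first. Cybb (ENSMUSG00000015340, X:9435252-9487771 on the minus strand of GRCm38) stood at 129 to 221 CPM in the 9 knockout libraries and at 899 to 2319 CPM in the 6 wild-type libraries. The ranges did not overlap (exact permutation p = 2.0e-04, two-sided, the smallest that the 5005 regroupings can give). These mix the ages and take the paired CD11b-high and CD11b-low libraries as independent. In the 12 CD11b-low libraries alone, regrouped within each age, p was 0.005, the smallest that 400 regroupings can give. At 4 weeks the level was 204 ± 18.6 CPM in knockout and 1795 ± 454 CPM in wild-type cells, a log2 difference of -3.14 (SE 0.25, adjusted p = 6.6e-06). At 12 weeks it was 163 ± 26.4 CPM in CD11b-low knockout and 1026 ± 172 CPM in wild-type cells, a log2 difference of -2.65 (SE 0.25, adjusted p = 2.1e-05). CD11b-high knockout cells held 149 ± 22.5 CPM. Counts cover the whole gene, and the labels do not say which part was removed.

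**Figure D1:**
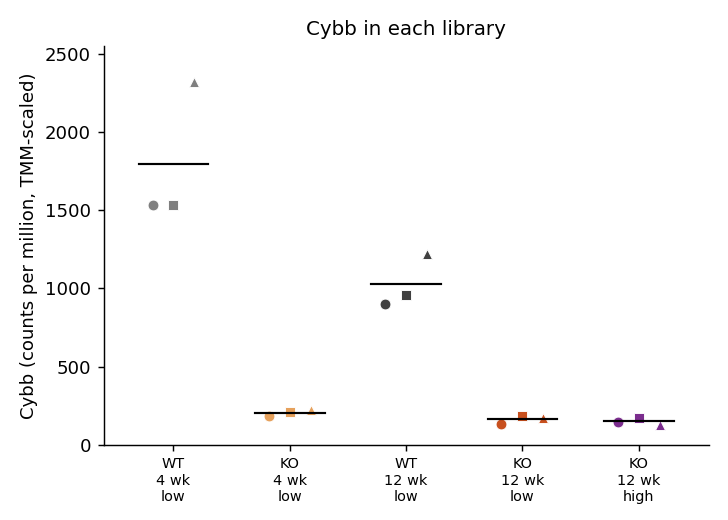
Cybb level in CPM on a linear axis from 0 for every library, by group, with circle, square and triangle for replicates 1, 2 and 3 and a black line at the group mean. The 9 knockout libraries lie between 129 and 221 CPM, and the 6 wild-type libraries between 899 and 2319 CPM.

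How adult CD11b-low macrophages differ without NOX2 was addressed by knockout against wild-type cells at 12 weeks. Of 13284 genes, 412 passed an adjusted p of 0.05, with 346 higher and 66 lower in the knockout, and 376 of them differed by more than 2-fold. Among genes at 10 CPM or more in 1 group, the largest rise was in Fstl1 (ENSMUSG00000022816), a secreted follistatin-like glycoprotein, at 381 ± 187 against 4.17 ± 0.275 CPM, a log2 fold change of 6.51 (SE 0.52, adjusted p = 2.7e-06). Mfge8 (ENSMUSG00000030605), which bridges apoptotic cells to phagocytes, rose to 743 ± 622 against 24.7 ± 11.3 CPM (30.1-fold). Anpep (ENSMUSG00000039062), the surface aminopeptidase CD13, rose to 34.0 ± 7.57 against 1.25 ± 0.181 CPM (27.1-fold). The T cell genes Cd3e, Cd3g, Pdcd1 and the chemokine receptor gene Cxcr6 rose to 18.4 ± 12.1, 18.5 ± 9.01, 14.9 ± 12.8 and 55.1 ± 35.7 CPM, from 0.461 ± 0.249, 0.619 ± 0.375, 0.379 ± 0.582 and 1.02 ± 0.0695 CPM. H2-M2, a nonclassical class I gene, rose to 177 ± 122 against 2.36 ± 1.77 CPM, Pla2g2d, a secreted phospholipase A2, to 20.2 ± 23.6 against 0.253 ± 0.251 CPM, and Fam20c, a kinase of the secretory pathway, to 10.3 ± 6.93 against 0.265 ± 0.364 CPM.

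The largest falls were in the globin genes Hbb-bt (9.24-fold, adjusted p = 0.0166), Hbb-bs (8.87-fold, 55.7 ± 24.1 against 494 ± 254 CPM), Hba-a2 (7.84-fold) and Hba-a1 (7.52-fold). Sftpc, the surfactant protein C gene of alveolar type II cells, fell from 30.1 ± 21 to 3.90 ± 2.73 CPM (adjusted p = 0.0490). Cybb, Inka1 (5.18-fold), Rcn3 (2.99-fold), the proapoptotic gene Bmf (2.88-fold) and the fatty acid binding protein gene Fabp1 (2.76-fold, 839 ± 117 against 2319 ± 914 CPM) completed the set. Of the sort markers, Itgam stood at 4.61 ± 1.58 against 1.57 ± 0.720 CPM (adjusted p = 0.0584), Itgax at 409 ± 101 against 316 ± 153 CPM, Siglecf at 240.2 ± 52.5 against 276 ± 54.9 CPM and Ptprc at 676 ± 195 against 503 ± 143 CPM, and none of them passed the test. The globin pairs and Ear1 with Ear2 are near-identical copies, so how their counts were divided between the copies is uncertain.

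The fixed lists were set against the other genes with camera at a preset correlation, and 21 of the 32 tested passed at 12 weeks, 17 higher and 4 lower in the knockout. None of the 21 passed with an estimated correlation. Of the 20 lipid-associated macrophage genes, 4 rose and 16 did not pass, against 10 higher adjusted over the list alone (adjusted p = 9.7e-07, and 0.129 with an estimated correlation). Among them the elastase Mmp12 rose from 8.05 ± 4.53 to 128 ± 50.2 CPM, the glycoprotein gene Gpnmb from 466 ± 196 to 2428 ± 850.0 CPM, and the tetraspanin gene Cd63 from 306 ± 45.6 to 1081 ± 552 CPM. Of 24 cholesterol biosynthesis genes, 4 rose and 20 did not pass, against 9 higher and 1 lower adjusted over the list alone (adjusted p = 1.5e-04, and 0.129 with an estimated correlation). The sterol sensor partner Insig1 rose 2.29-fold. In lipid uptake and storage, 4 rose and 18 did not pass, against 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0155, and 0.105 with an estimated correlation). The scavenger receptor gene Msr1 rose from 13.1 ± 3.80 to 42.1 ± 21.1 CPM and the cholesterol ester enzyme Soat1 from 199 ± 79.2 to 464 ± 151 CPM. For lysosome genes, 3 rose and 38 did not pass, against 7 higher adjusted over the list alone (adjusted p = 2.3e-05, and 0.105 with an estimated correlation). The proton pump subunit gene Atp6v1a rose 2.42-fold and the galactosidase gene Gla 2.47-fold. In apoptotic cell clearance, 2 rose and 18 did not pass, against 5 higher adjusted over the list alone (adjusted p = 5.5e-04, and 0.105 with an estimated correlation). Mfge8 and Cd93 (5.96-fold) rose. In matrix remodelling, 4 rose and 23 did not pass, against 12 higher adjusted over the list alone (adjusted p = 4.1e-07, and 0.0527 with an estimated correlation). The cathepsin K gene Ctsk rose from 1033 ± 358 to 4985 ± 1576 CPM and the membrane metalloproteinase Mmp14 from 0.0671 ± 0.116 to 5.24 ± 4.80 CPM.

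Inflammatory and interferon genes were also higher. Of the 28 tested cytokine and chemokine genes, 7 rose and 21 did not pass, against 12 higher and 2 lower adjusted over the list alone (adjusted p = 6.2e-07, and 0.105 with an estimated correlation). The chemokine Ccl9 rose from 46.2 ± 15.2 to 419 ± 164 CPM, Cxcl3 8.49-fold and Il1a 4.14-fold. Of 41 interferon response genes, 6 rose and 35 did not pass, against 12 higher adjusted over the list alone (adjusted p = 4.4e-09, and 0.0725 with an estimated correlation). The antiviral genes Oasl2 and Usp18 rose 11.2-fold and 5.79-fold. In the NF-kappaB list, 3 rose and 24 did not pass, against 3 higher adjusted over the list alone (adjusted p = 0.00947, and 0.115 with an estimated correlation). Tnip1 rose 2.00-fold and the adhesion gene Icam1 2.19-fold. Pattern recognition genes moved both ways: 4 rose, 2 fell and 22 did not pass, against 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.0143, and 0.256 with an estimated correlation). Clec4e rose 2.41-fold and Tlr13 2.83-fold, and Clec4a2 and Fpr2 fell. In the alternative activation list, 1 rose and 21 did not pass, against 2 higher adjusted over the list alone (adjusted p = 0.0447, and 0.460 with an estimated correlation). The chemokine gene Ccl17, also the riser of the dendritic cell list, rose 4.52-fold. Among monocyte-derived macrophage genes, 3 rose and 21 did not pass, against 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.0154, and 0.302 with an estimated correlation). Those included Tmem176a and Ly6c2, at 7.08 ± 2.76 and 1.06 ± 0.384 CPM in the knockout. In the cell cycle list, 6 rose and 32 did not pass, against 11 higher and 1 lower adjusted over the list alone (adjusted p = 3.2e-04, and 0.283 with an estimated correlation). The mitotic kinase gene Plk1 rose 2.85-fold and Ccnb1 2.09-fold. The oxidative phosphorylation list was lower as a group, and none of the 54 tested members passed by edgeR (22 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom), against none adjusted over the list alone (adjusted p = 9.5e-06, and 0.129 with an estimated correlation). Cox4i1 in that list stood at 1506 ± 392 against 2154 ± 319 CPM. Mitochondrial genes held 0.505 to 0.801% of the counts in CD11b-low knockout and 1.13 to 1.29% in wild-type libraries of this age, without overlap, and 0.773 to 0.945% and 0.738 to 1.17% at 4 weeks. In the immediate early and handling stress list, 1 fell and 21 did not pass, against 1 lower adjusted over the list alone (adjusted p = 0.0499, and 0.560 with an estimated correlation). Rhob fell 2.03-fold.

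Markers of other cell types moved with these groups. Of 19 T and NK cell markers, 9 rose and 10 did not pass, against 12 higher adjusted over the list alone (adjusted p = 1.8e-15, and 0.0527 with an estimated correlation). Lck and Trac rose 11.8-fold and 15.4-fold. The summed CPM of the list ran the other way, 1257 to 1312 CPM of the library total in knockout and 1385 to 1595 CPM in wild-type libraries. Cd2, named after its values were seen, made 1118 to 1260 and 1379 to 1585 CPM of it and did not pass. In the B and plasma cell list, 1 rose and 9 did not pass, against 3 higher adjusted over the list alone (adjusted p = 0.0154, and 0.106 with an estimated correlation). Blk stood at 5.43 ± 5.96 against 0.138 ± 0.239 CPM. In the dendritic cell list, 1 rose and 13 did not pass, against 5 higher adjusted over the list alone (adjusted p = 0.00367, and 0.129 with an estimated correlation). In the neutrophil list, 2 rose and 10 did not pass, against 4 higher adjusted over the list alone (adjusted p = 0.0274, and 0.129 with an estimated correlation). The neutrophil risers were Il1r2 (5.94-fold) and S100a8 (95.4 ± 53.5 against 34.1 ± 14.3 CPM). Of the 7 erythroid genes, 4 fell and 3 did not pass, against 5 lower adjusted over the list alone (adjusted p = 1.8e-07, and 0.106 with an estimated correlation). All that fell were globins. In the lung epithelial list, 1 fell and 15 did not pass, against 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.00168, and 0.115 with an estimated correlation). Sftpc was the gene that fell. Only Prg2 and Ear6 of the eosinophil list had enough counts to test, so the list was not tested. Its markers summed to 123 to 999 CPM of the library total in the 6 knockout libraries at 12 weeks and to 10.02 to 39.3 CPM in the other 9. In CD11b-low groups Ear6 made nearly all of the sum.

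The sexes of the pooled mice were not among the labels. Xist, the transcript of the inactive X chromosome, stood at 17.8, 0.0295 and 10.7 CPM of the library total in CD11b-low knockout replicates 1, 2 and 3 and at 0 to 0.0853 CPM in the wild-type libraries of that age.

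Several groups did not pass. In the alveolar macrophage identity list, 1 of 26 members rose and 3 fell (3 and 4 adjusted over the list alone, adjusted p = 0.808). The ribonuclease genes Ear1 and Ear2 fell 2.57-fold and 2.33-fold, and the transcription factor gene Bhlhe41 rose from 79.1 ± 47.4 to 423 ± 256 CPM. MHC class II presentation (adjusted p = 0.742), cholesterol efflux and LXR targets (adjusted p = 0.685), fatty acid oxidation (adjusted p = 0.742) and glycolysis and hypoxia (adjusted p = 0.0588) did not pass. Nor did NRF2 targets (adjusted p = 0.404), antioxidant enzymes (adjusted p = 0.236), the unfolded protein response (adjusted p = 0.742), TGF-beta receptor and SMAD targets (adjusted p = 0.789) and sex-linked markers (adjusted p = 0.789). Among the 9 NADPH oxidase subunit genes Cybb alone passed (adjusted p = 0.231 for the list), and the list's median log2 fold change of 0.23 and mean of -0.23 differed in sign. So did those of MHC class II presentation (-0.02 and 0.08), of fatty acid oxidation (-0.04 and 0.03) and of the TGF-beta list (-0.25 and 0.13).

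The count of 412 genes was 189 when the fit held only the 2 groups, 864 by DESeq2 with its own filter and 880 by DESeq2 on the genes kept here, 1090 with no filter on low counts, and 230, 257 and 271 without CD11b-low knockout replicate 2, wild-type replicate 1 and wild-type replicate 2. Of the 20 genes with the largest changes, 18 passed with only the 2 groups in the fit (not Bmf and Fabp1) and 12 by limma voom with library weights, which lost the globins, Sftpc, Pla2g2d, Pdcd1 and Bmf. Sftpc missed the threshold without any 1 of the 6 libraries (adjusted p = 0.0556 to 0.117, log2 fold change -3.57 to -2.28), as did Ccl17. Ly6c2 missed it without any 1 of 5, Tmem176a, Soat1, Insig1, Ccnb1, S100a8 and Bmf without any 1 of 4, and the globins Hbb-bs and Hbb-bt, Icam1, Plk1, Rhob and Blk without any 1 of 3. Folds moved by more than 1.5 times (log2 given) without knockout replicate 1 (H2-M2 5.50, Pla2g2d 4.59, Fam20c 4.58, Mfge8 3.96, Mmp14 5.18, Cd93 1.96) or knockout replicate 2 (Cd3e 4.58, Pdcd1 4.23, Blk 3.67). They moved without wild-type replicate 1 (H2-M2 7.02, Fam20c 7.42), replicate 2 (Pla2g2d 7.51, Pdcd1 8.31, Cd3g 5.50, Oasl2 4.07, Mmp14 5.59) or replicate 3 (Bhlhe41 3.01, Cxcl3 4.25, Usp18 3.16). Mmp14 without wild-type replicate 1 and Blk without replicate 2 had 0 wild-type counts left. The list calls for immediate early, neutrophil, B and plasma cell, monocyte-derived, alternative activation, pattern recognition, lipid uptake and NF-kappaB genes each ended without some single library, while 13 of 21 held without any.

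**Figure D2:**
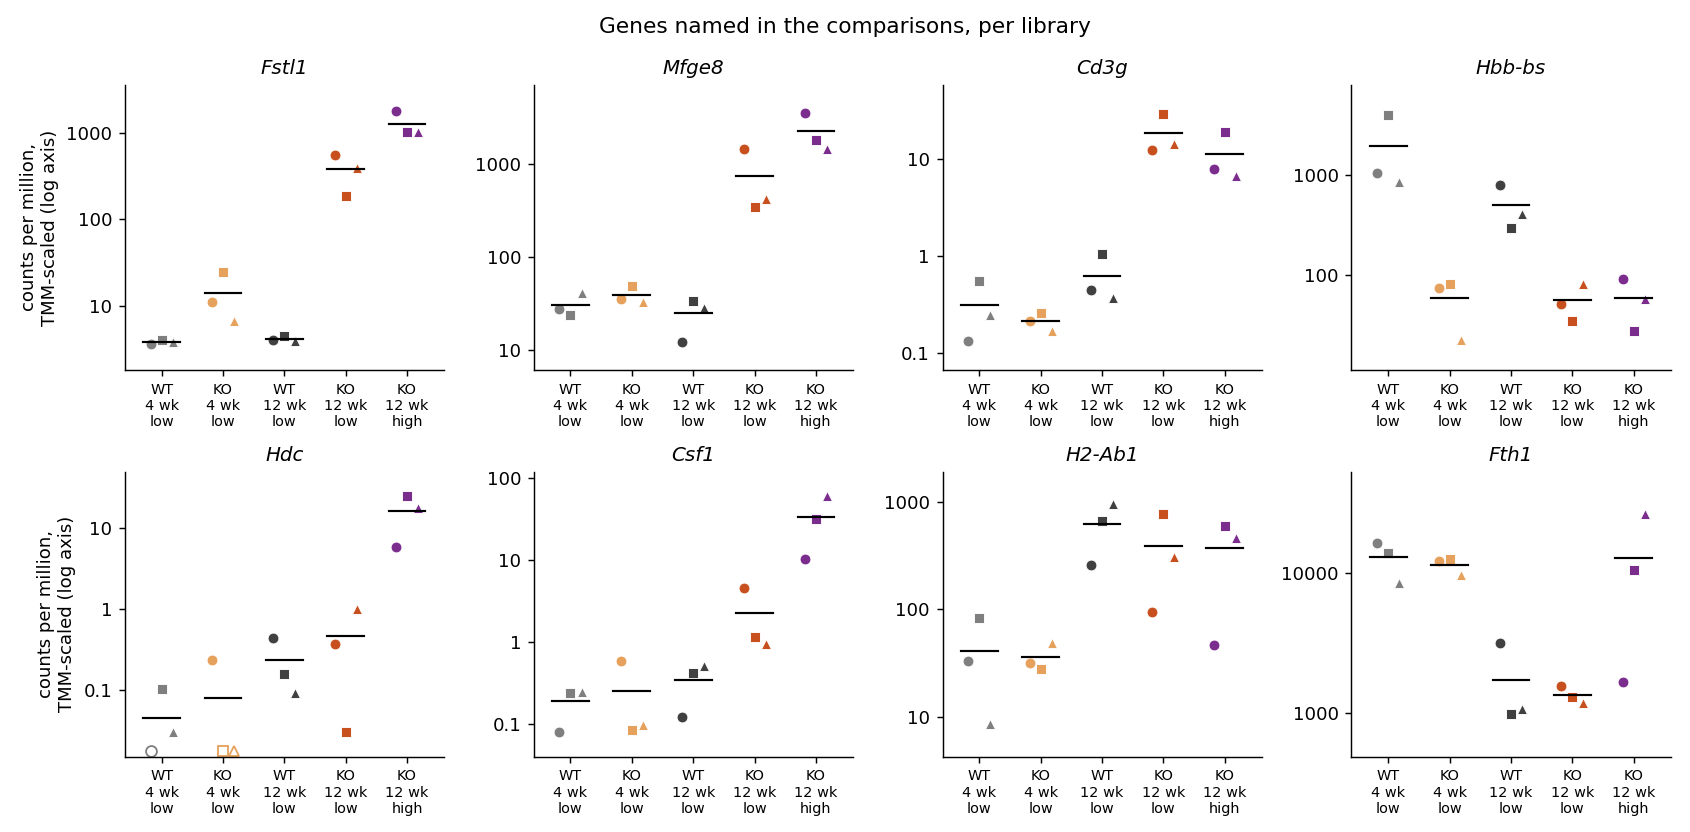
Level in CPM on a log axis of Fstl1, Mfge8, Cd3g, Hbb-bs, Hdc, Csf1, H2-Ab1 and Fth1 in every library by group, with circle, square and triangle for replicates 1, 2 and 3, a black line at the mean, and open symbols at the bottom for 0 counts (Hdc). Fstl1 averages 381 CPM in CD11b-low knockout cells at 12 weeks and 4.17 CPM in wild-type cells of that age.

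The same genotype comparison at 4 weeks asks whether the difference was present in young mice. There 13 genes passed, with 2 higher and 11 lower in the knockout, while 199 had an unadjusted p under 0.05 and 664.2 would by chance. Besides Cybb, the genes that fell were mostly those of red blood cells and their precursors. Hbb-bs fell from 1933 ± 1718 to 59.4 ± 32.1 CPM (32.5-fold, adjusted p = 0.00636), and Hba-a1, Hba-a2 and Hbb-bt fell 32.7-fold, 32.3-fold and 37.2-fold. Alas2, the erythroid enzyme of heme synthesis, fell from 271 ± 245 to 8.49 ± 4.32 CPM. The carbonic anhydrase gene Car2 (62.3-fold), Tent5c (11.1-fold) and Bpgm (6.11-fold), an enzyme of red cell glycolysis, also fell, as did Tspo2, which lies outside the rule for naming. The higher genes, Evx2 and Dscaml1, were few-count genes outside the rule for naming, and are named after their values were seen. Evx2 had 18 to 32 counts in the knockout and 0 in every wild-type library, at least 6.71-fold higher over a floor of 3 counts in each wild-type library, which covers counting error only. Dscaml1 had 55 to 59 counts in the knockout libraries and 0 to 1 in the wild-type libraries.

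The erythroid list moved most at 4 weeks. Of its 7 genes, 5 fell and 2 did not pass, against 7 lower adjusted over the list alone (adjusted p = 1.7e-86, and 1.7e-04 with an estimated correlation). Its genes summed to 52.6 to 171 CPM of the library total in knockout and 1812 to 8333 CPM in wild-type libraries, wild-type replicate 2 being the highest. The NADPH oxidase list was lower through Cybb (adjusted p = 3.9e-05, and 0.0113 with an estimated correlation), and the other 8 members did not pass. Lung epithelial (adjusted p = 2.6e-06, and 0.0481 with an estimated correlation) and B and plasma cell markers (adjusted p = 0.00354, and 0.0481 with an estimated correlation) were lower as groups without a member passing by edgeR, with 4 and 2 members at an unadjusted p under 0.05 and none by DESeq2 or voom. Igkc in the latter stood at 0.0980 ± 0.0470 against 0.783 ± 0.446 CPM. Monocyte-derived macrophage (adjusted p = 0.00740, and 0.410 with an estimated correlation) and cholesterol biosynthesis genes (adjusted p = 0.0168, and 0.457 with an estimated correlation) were lower at the preset correlation. NF-kappaB targets (adjusted p = 0.0168, and 0.260 with an estimated correlation), matrix remodelling (adjusted p = 0.0302, and 0.410 with an estimated correlation), sex-linked markers (adjusted p = 0.0168, and 0.402 with an estimated correlation) and cytokine genes (adjusted p = 0.0168, and 0.457 with an estimated correlation) were higher. The cytokine list's median (0.07) and mean (-0.05) differed in sign. No member of these 6 lists passed by edgeR, where at most 5 had an unadjusted p under 0.05, 1 passed by DESeq2 and 0 by voom.

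The count was 4 with only the 2 groups in the fit, where of the 10 named genes Cybb alone still passed, 22 by DESeq2 (24 on the genes kept here), 73 with no filter, and 7, 4 and 7 without knockout replicates 1, 2 and 3. Without wild-type replicate 2, log2 fold changes were -3.64 for Car2, -3.99 for Hbb-bs, -4.07 for Hbb-bt, -4.18 for Hba-a1, -4.14 for Hba-a2 and -3.94 for Alas2. Those of Tent5c (-2.40) and Bpgm (-1.50) then missed the threshold (adjusted p = 0.108 for both), as they did without any 1 knockout library, where Car2 missed it too. List calls numbered 2 by fry, 5 without knockout replicate 2 and 6 without wild-type replicate 3, and 3 of 10 held without any single library.

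Both ages shared Cybb, Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2, lower, and Evx2 and Dscaml1, higher. Independent lists would share 0.0547 lower and 0.0521 higher genes. The 2 comparisons share no library, and their log2 fold changes correlated across genes with r = 0.0861 (rho = 0.0972), genes not being independent replicates. The 11 genes lower at 4 weeks were lower as a set at 12 weeks (camera p = 1.1e-10, and p = 0.0160 with an estimated correlation). The 5 passing singly were Cybb and globins, and no test left them out. Between CD11b-high and CD11b-low knockout cells the 11 gave p = 0.185, and p = 0.563 with an estimated correlation. By DESeq2 both ages shared 12 genes.

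Whether the genotype difference itself differed between the ages was tested as an interaction. It passed in 33 genes, all with a more positive knockout effect at 12 weeks. Cxcr6 had a difference between the effects of 7.55 on the log2 scale (adjusted p = 0.00453), with 0.195 CPM in knockout and 0.686 CPM in wild-type cells at 4 weeks. The difference was 4.63 for Fstl1 (adjusted p = 0.00453), 5.36 for Cd3g, 4.57 for Mfge8, 3.51 for Mmp12 and 4.25 for Lck. Ear6, a ribonuclease gene with near-identical relatives, differed by 4.84, at 349.9 ± 295 against 13.2 ± 2.94 CPM at 12 weeks. Tent5c, which fell at 4 weeks, differed by 4.82 and stood at 3.63 ± 0.823 against 1.43 ± 1.03 CPM at 12 weeks.

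Of the 32 lists, 18 passed the interaction test, 17 with a more positive effect at 12 weeks and oxidative phosphorylation with a more negative one. None passed with an estimated correlation. In T and NK cell markers, 2 differed upwards and 17 did not pass, against 12 higher adjusted over the list alone (adjusted p = 2.5e-17, and 0.0508 with an estimated correlation). In interferon response, none of the 41 tested members passed by edgeR (13 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom), against 9 higher adjusted over the list alone (adjusted p = 7.2e-09, and 0.0743 with an estimated correlation). In cholesterol biosynthesis, none of the 24 tested members passed by edgeR (11 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom), against 6 higher adjusted over the list alone (adjusted p = 1.7e-06, and 0.117 with an estimated correlation). In lipid-associated macrophage genes, 1 differed upwards and 19 did not pass, against 2 higher adjusted over the list alone (adjusted p = 1.7e-05, and 0.165 with an estimated correlation). Mmp12 was the gene that differed. Other lists that passed were monocyte-derived macrophage (adjusted p = 6.5e-04), lipid uptake and storage (0.0311), glycolysis (0.0435), oxidative phosphorylation (4.5e-04), cytokines (1.4e-04), matrix remodelling (2.3e-04), lysosome (8.8e-05), cell cycle (9.9e-04), apoptotic cell clearance (0.00435), pattern recognition (0.00435), neutrophil markers (0.00364), B and plasma cell markers (0.00161) and dendritic cell markers (0.00409). At most 1 member of each passed by edgeR, at most 10 had an unadjusted p under 0.05, and at most 4 passed by DESeq2 and 1 by voom. In erythroid markers, none of the 7 tested members passed by edgeR (7 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom), against 7 higher adjusted over the list alone (adjusted p = 7.0e-06, and 0.157 with an estimated correlation). The 33 genes were 3 without 4-week knockout replicate 3, 13 without 4-week wild-type replicate 2, and 21 without any of 12-week knockout replicate 1, wild-type replicate 1 or wild-type replicate 3. They were 151 by DESeq2 and 321 with no filter, and 4 of the 5 named first by size missed the threshold with voom, all but Cd3g. Named differences moved by more than 1.5 times without 4-week wild-type replicate 2 (Cxcr6 6.91, Cd3g 4.68, Tent5c 3.75) or replicate 1 (Lck 3.58), without 4-week knockout replicate 2 (Fstl1 5.31) or replicate 1 (Mmp12 4.15), without 12-week knockout replicate 1 (Ear6 3.90, Mfge8 3.62) or replicate 2 (Cxcr6 6.96), and without 12-week wild-type replicate 1 (Tent5c 5.58) or replicate 2 (Cd3g 6.00). Mmp12, Lck and Ear6 missed the threshold without any 1 of 9, 8 and 6 of the 12 libraries.

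What sets CD11b-high macrophages of adult knockout mice apart from the CD11b-low cells was addressed next. Between these groups 92 genes passed, 76 higher and 16 lower in CD11b-high cells, and all 92 differed by more than 2-fold. Itgam (ENSMUSG00000030786), the gene of the sorted antigen, rose from 4.61 ± 1.58 to 60.2 ± 28.9 CPM (13.1-fold, SE of log2 0.44, adjusted p = 0.00102). Hdc, which makes histamine, rose from 0.469 ± 0.499 to 16.2 ± 9.70 CPM, the monocyte chemoattractant Ccl7 from 3.10 ± 0.989 to 104 ± 83.0 CPM, and Npy, neuropeptide Y, from 1.05 ± 0.520 to 19.1 ± 8.50 CPM. The macrophage growth factor Csf1 (ENSMUSG00000014599) rose from 2.24 ± 2.05 to 33.8 ± 24.9 CPM, the complement gene C1qb from 1.48 ± 0.676 to 39.5 ± 34.8 CPM, the calprotectin gene S100a9 from 2.27 ± 1.37 to 42.9 ± 24.7 CPM and the decoy receptor gene Il1r2 from 2.89 ± 1.03 to 37.9 ± 19.9 CPM. The protease genes Asprv1 and Mmp13 rose 31.4-fold and 27.1-fold.

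The largest fall was in Cd300e (3.33-fold). The peptide gene Gal fell from 546 ± 102 to 177 ± 47.8 CPM (adjusted p = 0.00527), the formyl peptide receptors Fpr1 and Fpr2 2.45-fold and 2.16-fold, and the peptide loading gene H2-DMa from 1106 ± 115 to 499 ± 93.3 CPM. Smim5, the centromere gene Cenpm, Cpne5, the short-chain fatty acid receptor gene Ffar2 and Pilra fell 2.34-fold to 2.75-fold. Cybb (149 ± 22.5 against 163 ± 26.4 CPM, adjusted p = 0.926), Itgax (601 ± 141 against 409 ± 101 CPM), Siglecf (190.3 ± 17.4 against 240.2 ± 52.5 CPM) and Ptprc (548 ± 147 against 676 ± 195 CPM) did not pass.

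Of 32 lists, 17 passed, 14 higher and 3 lower in CD11b-high cells, and 7 of them also passed with an estimated correlation. Those were monocyte-derived macrophage, interferon response, matrix remodelling, cell cycle, apoptotic cell clearance, neutrophil and dendritic cell genes. Of 24 monocyte-derived macrophage genes, 3 rose, 1 fell and 20 did not pass, against 11 higher and 1 lower adjusted over the list alone (adjusted p = 1.3e-08, and 0.0476 with an estimated correlation). Itgam, C1qa (from 0.0509 ± 0.0334 to 4.32 ± 3.25 CPM) and C1qb rose, and the Fc receptor gene Fcgr1 fell 2.02-fold. In matrix remodelling, 6 rose and 21 did not pass, against 10 higher and 1 lower adjusted over the list alone (adjusted p = 9.3e-08, and 0.0476 with an estimated correlation). Mmp12 rose from 128 ± 50.2 to 1344 ± 692 CPM, the thrombospondin gene Thbs1 from 1.04 ± 1.12 to 56.8 ± 49.3 CPM and Adam8 7.82-fold. In apoptotic cell clearance, 2 rose and 18 did not pass, against 4 higher adjusted over the list alone (adjusted p = 3.4e-05, and 0.0476 with an estimated correlation). C1qa and C1qb rose. In interferon response, 1 rose and 40 did not pass, against 6 higher adjusted over the list alone (adjusted p = 1.3e-08, and 0.0476 with an estimated correlation). Usp18 rose 5.06-fold. The cell cycle list was lower, and none of the 38 tested members passed by edgeR (15 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom), against 1 lower adjusted over the list alone (adjusted p = 2.0e-14, and 0.0476 with an estimated correlation). Rrm2 stood at 103 ± 43.1 against 129 ± 41.3 CPM and Rrm1 at 86.4 ± 28.5 against 114 ± 29.5 CPM.

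Of 12 neutrophil markers, 3 rose and 9 did not pass, against 8 higher and 1 lower adjusted over the list alone (adjusted p = 3.7e-10, and 0.00379 with an estimated correlation). Il1r2, S100a9 and Hdc rose, in cells sorted as Ly6G-. In the dendritic cell list, none of the 14 tested members passed by edgeR (9 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by voom), against 5 higher adjusted over the list alone (adjusted p = 2.4e-06, and 0.0476 with an estimated correlation). The other lists passed at the preset correlation alone. In cytokines and chemokines, 5 rose and 23 did not pass, against 10 higher adjusted over the list alone (adjusted p = 2.8e-08, and 0.0524 with an estimated correlation). Ccl4 rose 11.9-fold and Cxcl16 3.70-fold. In lipid-associated macrophage genes, 2 rose and 18 did not pass, against 4 higher adjusted over the list alone (adjusted p = 1.8e-05, and 0.160 with an estimated correlation). Spp1, osteopontin, rose from 2127 ± 742 to 5300.2 ± 1330.3 CPM. In MHC class II presentation, lower as a group, 1 fell and 14 did not pass, against 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.0118, and 0.224 with an estimated correlation). Alveolar macrophage identity was lower (adjusted p = 1.9e-04, and 0.0868 with an estimated correlation). None of its members passed by edgeR, while 6 had an unadjusted p under 0.05, 3 passed by DESeq2 and 4 by voom. Cholesterol biosynthesis (adjusted p = 2.4e-05, and 0.115 with an estimated correlation), alternative activation (adjusted p = 3.2e-04, and 0.199 with an estimated correlation), NF-kappaB targets (adjusted p = 0.00143, and 0.0646 with an estimated correlation), lung epithelial markers (adjusted p = 0.00357, and 0.137 with an estimated correlation), the unfolded protein response (adjusted p = 0.00845, and 0.160 with an estimated correlation) and lipid uptake and storage (adjusted p = 0.0192, and 0.0646 with an estimated correlation) were higher. No member of these 6 lists passed by edgeR, while 5 to 11 per list had an unadjusted p under 0.05, and at most 3 passed by DESeq2 and 2 by voom. Of NRF2 targets, a list that did not pass (adjusted p = 0.482), the ferritin heavy chain gene Fth1 and the growth inhibitor gene Osgin1 passed at 3.25 and 2.73 on the log2 scale, named after their values were seen. Fth1 was at 10588 and 26453 CPM in CD11b-high replicates 2 and 3, but 1678 CPM in replicate 1, against 1186 to 1563 CPM in CD11b-low cells. Neither gene passed without CD11b-high replicate 3 (log2 2.18 and 2.08) or with only the 2 groups in the fit. Fth1 also missed by voom and with the replicate block. T and NK cell markers did not pass (adjusted p = 0.135), nor did erythroid markers (adjusted p = 0.976).

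The 92 genes were 18 with only the 2 groups in the fit and 533 with no filter, and 2 to 247 without any 1 library. Of the 20 genes named first by size, 4 passed with only the 2 groups in the fit (Asprv1, Npy, Il1r2 and Itgam). With the replicate number as a block Mmp13 and Csf1 missed the threshold (adjusted p = 0.0671 and 0.0554). Hdc, Mmp13, Fcgr1, Thbs1, Adam8, Cenpm, Cpne5 and Fth1 missed it without any 1 of 5 of the 6 libraries, Csf1, Spp1, Cxcl16, Usp18, Cd300e, Ffar2, Fpr1, Fpr2, H2-DMa and Osgin1 without any 1 of 4, and Ccl7, Smim5 and Pilra without any 1 of 3. Folds moved by more than 1.5 times (log2 given) without CD11b-high replicate 2 (Mmp13 3.15, C1qb 3.93, Adam8 2.33) or replicate 3 (Csf1 3.21, Thbs1 5.14), and without CD11b-low replicate 1 (Csf1 4.99), replicate 2 (C1qa 6.89) or replicate 3 (Hdc 6.33, Thbs1 7.06). The list calls for lipid uptake, MHC class II, alternative activation and the unfolded protein response each ended without some single library, and the other 13 held.

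CD11b-high knockout cells were also set against the only wild-type group of that age, which was CD11b-low, so genotype and subset differ together. Here 1970 genes passed, 1226 higher and 744 lower in the knockout cells. Npy rose from 0.0134 ± 0.0232 to 19.1 ± 8.50 CPM (adjusted p = 5.6e-07), the fusion gene Dcstamp from 0.0258 ± 0.0234 to 19.1 ± 12.8 CPM, Thbs1 from 0.103 ± 0.0159 to 56.8 ± 49.3 CPM and the chemokine Ccl8 from 0.0258 ± 0.0234 to 21.3 ± 30.1 CPM. Retnla rose from 0.0527 ± 0.0251 to 41.5 ± 67.2 CPM. The globins and Sftpc fell most, Hbb-bs from 494 ± 254 to 58.9 ± 31.9 CPM and Sftpc from 30.1 ± 21 to 4.14 ± 2.35 CPM. Itgam rose 38.5-fold and Itgax 1.90-fold, while Siglecf (190.3 ± 17.4 against 276 ± 54.9 CPM) did not pass.

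Of 32 lists, 17 passed, 15 higher and 2 lower. With an estimated correlation, 9 passed. In interferon response, 24 rose and 17 did not pass, against 26 higher adjusted over the list alone (adjusted p = 8.6e-14, and 0.0237 with an estimated correlation). Oasl2 rose 35.3-fold and Usp18 29.3-fold. In cholesterol biosynthesis, 14 rose and 10 did not pass, against 15 higher and 1 lower adjusted over the list alone (adjusted p = 4.7e-08, and 0.040 with an estimated correlation). Insig1 and Cyp51 rose 4.39-fold and 3.42-fold. In cytokines and chemokines, 17 rose, 2 fell and 9 did not pass, against 19 higher and 2 lower adjusted over the list alone (adjusted p = 1.3e-10, and 0.0359 with an estimated correlation). Ccl9 rose from 46.2 ± 15.2 to 1331 ± 183 CPM. In matrix remodelling, 16 rose, 1 fell and 10 did not pass, against 17 higher and 1 lower adjusted over the list alone (adjusted p = 4.4e-10, and 0.0209 with an estimated correlation). Neutrophil markers (adjusted p = 0.0209 with an estimated correlation), apoptotic cell clearance (adjusted p = 0.0334 with an estimated correlation), NF-kappaB targets (adjusted p = 0.0379 with an estimated correlation), lipid uptake and storage (adjusted p = 0.0258 with an estimated correlation) and dendritic cell markers (adjusted p = 0.040 with an estimated correlation) were the others. Lipid-associated macrophage genes (adjusted p = 1.1e-09, and 0.0606 with an estimated correlation), with 11 of 20 rising, T and NK cell markers (adjusted p = 4.5e-08, and 0.0653 with an estimated correlation), with 10 of 19 rising and 1 falling, monocyte-derived genes (adjusted p = 1.5e-06, and 0.0822 with an estimated correlation) and lysosome genes (adjusted p = 2.6e-05, and 0.0696 with an estimated correlation) passed at the preset correlation alone. So did alternative activation (adjusted p = 0.00102, and 0.266 with an estimated correlation), B and plasma cell markers (adjusted p = 0.0379, and 0.143 with an estimated correlation), and, lower, erythroid markers (adjusted p = 2.3e-05, and 0.152 with an estimated correlation) and oxidative phosphorylation (adjusted p = 2.3e-05, and 0.152 with an estimated correlation), in which 9 of 54 fell. Lists that did not pass (adjusted p = 0.0519 to 0.835) held genes past the threshold, higher and lower: alveolar macrophage identity (4 and 6), cholesterol efflux (3 and 2), fatty acid oxidation (1 and 2), glycolysis (3 and 1), MHC class II presentation (3 and 4), NRF2 targets (3 and 2), antioxidant enzymes (2 and 4), cell cycle (0 and 3), pattern recognition (10 and 6), unfolded protein response (4 and 2), immediate early genes (1 and 2), TGF-beta targets (3 and 2) and lung epithelial markers (2 and 3).

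Both 12-week knockout subsets were compared with the same 3 wild-type libraries. They shared 330 higher and 57 lower genes, where independent lists would share 31.9 and 3.70. Log2 fold changes correlated across genes at r = 0.819 (rho = 0.750), against 0.506 ± 0.0103 in 20 simulations of unchanged groups with shared controls, and their covariance was 1.14 against 0.122 ± 0.00397. The simulations leave out the pairing of the real subsets by replicate number. Halving the 3 controls would leave fewer than 2 libraries on a side, so part of the excess may come from the shared controls and the pairing. The 1970 genes were 793 with only the 2 groups in the fit and 952 without CD11b-high replicate 2, and DESeq2 shared 756 genes between the subsets (768 on the genes kept here). Retnla missed the threshold with only the 2 groups, with the block and with voom, which also lost Ccl8, Thbs1, Hbb-bs and Hbb-bt. Folds moved by more than 1.5 times (log2 given) without CD11b-high replicate 2 (Retnla 5.61, Ccl8 7.11, Dcstamp 8.63) or replicate 3 (Thbs1 8.43), and without wild-type replicate 2 (Npy 9.55, Oasl2 5.73) or replicate 3 (Usp18 5.49, and Sftpc -2.19, which then missed the threshold). Itgax missed it without any 1 of 5 of the 6 libraries (log2 0.69 to 1.08) and Retnla without any 1 of 3. Npy without wild-type replicate 1 had 0 wild-type counts left. The B and plasma cell call ended without any 1 of 5 libraries.

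**Figure D3:**
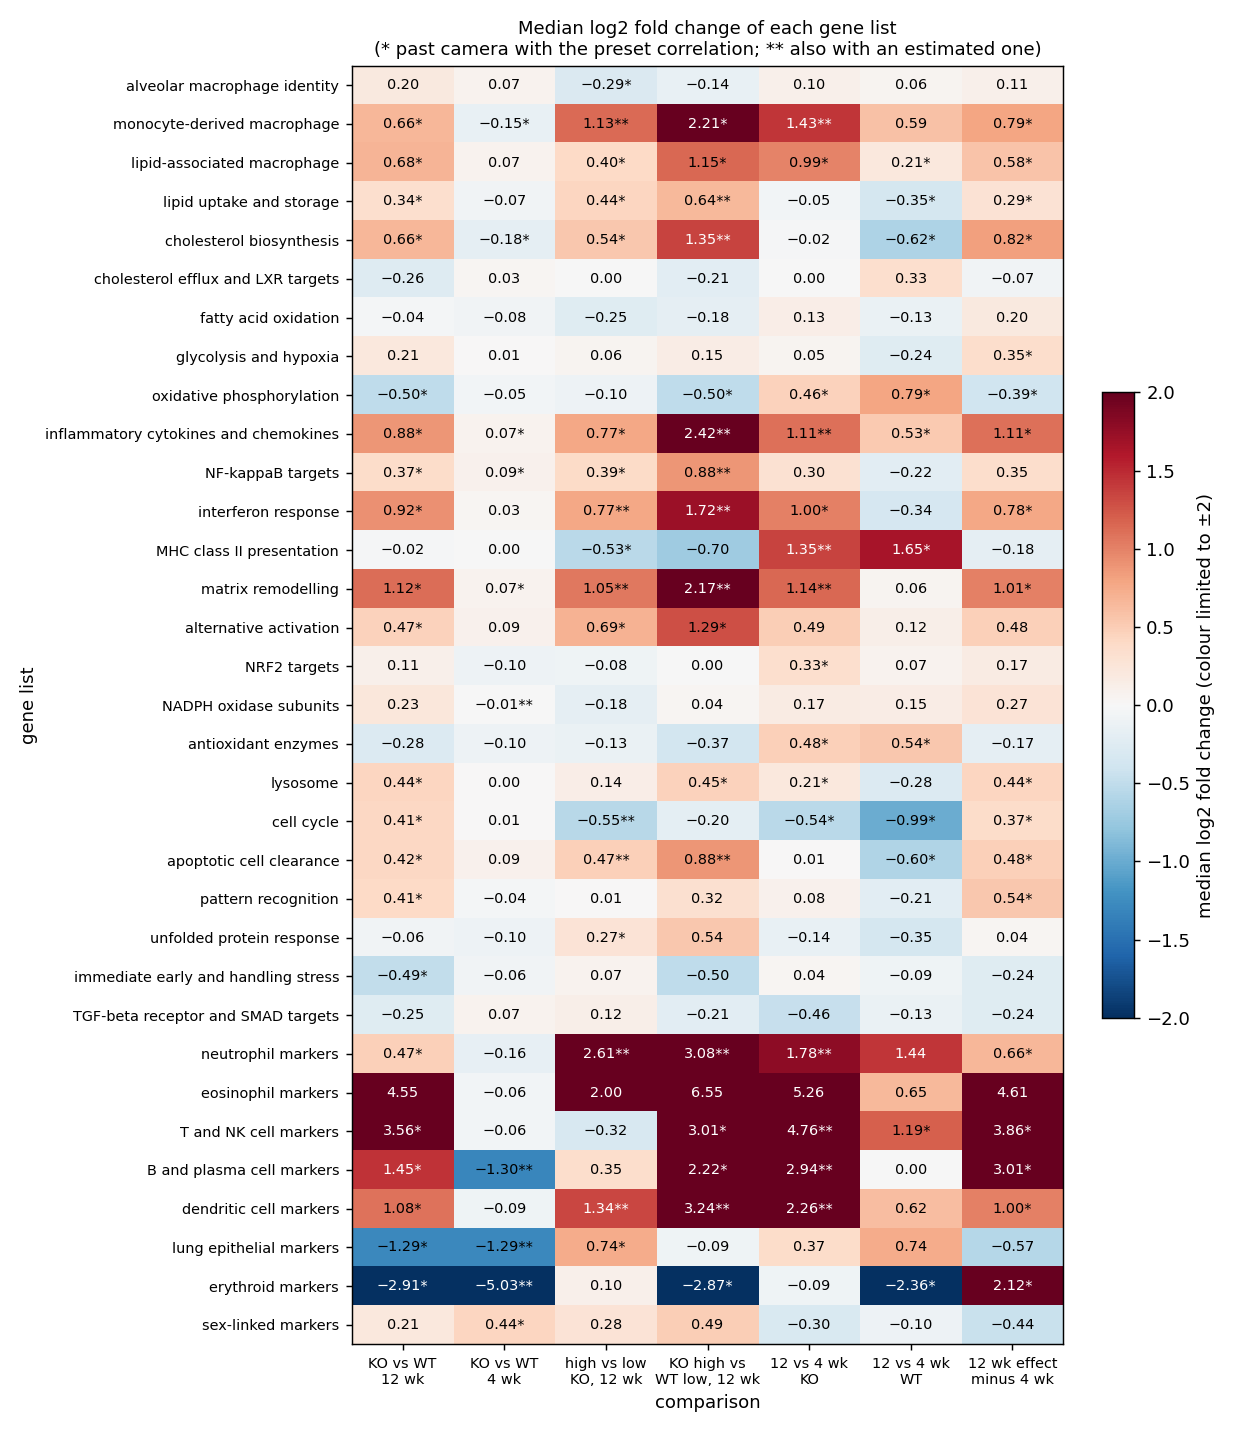
Median log2 fold change of each of the 33 gene lists (vertical axis) in each of the 7 comparisons (horizontal axis), with the colour scale limited to ±2. One star marks lists past an adjusted p of 0.05 with camera at the preset correlation, and a double star those that also pass with an estimated correlation, 9 of them in CD11b-high knockout against CD11b-low wild-type cells.

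How the macrophages change between 4 and 12 weeks was addressed in each genotype, age and the time of processing being inseparable here. In wild-type cells 2282 genes passed, 1167 higher and 1115 lower at 12 weeks. The MHC class II genes led the rises: H2-Aa (ENSMUSG00000036594) rose from 69.3 ± 55.7 to 1805 ± 348 CPM (26.1-fold, adjusted p = 4.6e-04), H2-Eb1 from 18.4 ± 14.5 to 334 ± 148 CPM, the invariant chain Cd74 from 548 ± 407 to 9405 ± 1463 CPM and H2-Ab1 from 41.4 ± 37.8 to 625 ± 346 CPM. Hr rose 13.3-fold. Fth1 (ENSMUSG00000024661), the ferritin heavy chain, fell from 13024 ± 4057 to 1737 ± 1231 CPM, the antiviral gene Rsad2 12.5-fold, Alas2 from 271 ± 245 to 27.0 ± 9.81 CPM, Tent5c 12.7-fold and Car2 16.5-fold. Cybb fell from 1795 ± 454 to 1026 ± 172 CPM (log2 fold change -0.81, adjusted p = 0.0264). Itgam (1.57 ± 0.720 against 1.48 ± 0.582 CPM), Itgax (316 ± 153 against 328 ± 33.3 CPM), Siglecf (276 ± 54.9 against 288 ± 27.7 CPM) and Ptprc (503 ± 143 against 768 ± 60.1 CPM) did not pass.

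Of 32 lists 11 passed in wild-type cells, 6 higher and 5 lower at 12 weeks, and none passed with an estimated correlation. Of 15 MHC class II genes, 8 rose and 7 did not pass, against 13 higher adjusted over the list alone (adjusted p = 9.9e-11, and 0.0518 with an estimated correlation). Of 54 oxidative phosphorylation genes, 31 rose, 2 fell and 21 did not pass, against 32 higher and 4 lower adjusted over the list alone (adjusted p = 1.2e-09, and 0.200 with an estimated correlation). Ndufs8 and Uqcrh rose 2.21-fold and 2.69-fold. Of 38 cell cycle genes, 18 fell and 20 did not pass, against 3 higher and 24 lower adjusted over the list alone (adjusted p = 1.6e-08, and 0.269 with an estimated correlation). Plk1 fell 4.85-fold and the topoisomerase Top2a from 103 ± 3.59 to 36.1 ± 8.75 CPM. In cholesterol biosynthesis, 1 rose, 10 fell and 13 did not pass, against 3 higher and 11 lower adjusted over the list alone (adjusted p = 1.3e-04, and 0.269 with an estimated correlation). Hmgcs1 fell from 181 ± 64.9 to 48.1 ± 17.2 CPM. In antioxidant enzymes, 8 rose, 2 fell and 10 did not pass, against 10 higher and 2 lower adjusted over the list alone (adjusted p = 0.00365, and 0.269 with an estimated correlation). In apoptotic cell clearance, 6 fell and 14 did not pass, against 6 lower adjusted over the list alone (adjusted p = 0.0259, and 0.291 with an estimated correlation). Cd93 fell 3.42-fold. Lipid uptake and storage was lower (adjusted p = 0.040, and 0.200 with an estimated correlation), 7 members falling and 2 rising. All 7 erythroid genes fell (adjusted p = 2.5e-04, and 0.388 with an estimated correlation), Slc4a1 from 3.67 ± 4.28 to 0.0453 ± 0.0479 CPM. Lipid-associated macrophage (adjusted p = 0.040, and 0.639 with an estimated correlation), cytokine (adjusted p = 0.040, and 0.572 with an estimated correlation) and T and NK cell genes (adjusted p = 0.040, and 0.599 with an estimated correlation) were higher. In the alveolar macrophage identity list, which did not pass (adjusted p = 0.511), Ear1 rose 2.53-fold and Bhlhe41 fell from 444 ± 121 to 79.1 ± 47.4 CPM. Lists that did not pass (adjusted p = 0.0511 to 0.962) held genes past the threshold, higher and lower: alveolar macrophage identity (6 and 2), monocyte-derived macrophage (5 and 1), cholesterol efflux (4 and 0), fatty acid oxidation (3 and 4), glycolysis (0 and 5), NF-kappaB targets (3 and 2), interferon response (3 and 4), matrix remodelling (3 and 0), alternative activation (2 and 1), NRF2 targets (5 and 3), lysosome (3 and 4), pattern recognition (5 and 7), unfolded protein response (2 and 2), neutrophil markers (2 and 1), dendritic cell markers (2 and 1) and lung epithelial markers (3 and 1).

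In knockout cells 915 genes passed between the ages, 639 higher and 276 lower at 12 weeks. The largest rises were in Pdcd1 (from 0.0174 ± 0.0152 to 14.9 ± 12.8 CPM), Cxcr6 (from 0.195 ± 0.0999 to 55.1 ± 35.7 CPM, adjusted p = 3.7e-05), Pla2g2d (from 0.193 ± 0.198 to 20.2 ± 23.6 CPM), Cd3g (86.6-fold) and Cd3e (73.8-fold). Fth1 fell from 11454 ± 1582 to 1353 ± 192 CPM, and Map4k1, Rem1, the ATP synthase gene Atp5d and Inka1 fell 6.58-fold, 5.65-fold, 5.32-fold and 5.20-fold. Cybb (163 ± 26.4 against 204 ± 18.6 CPM) did not pass, and Itgam rose from 1.53 ± 0.397 to 4.61 ± 1.58 CPM.

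Of 32 lists 15 passed in knockout cells, 14 higher and 1 lower, and 8 passed with an estimated correlation. Of 19 T and NK cell markers, 13 rose and 6 did not pass, against 18 higher adjusted over the list alone (adjusted p = 5.3e-24, and 0.0211 with an estimated correlation). Trac rose from 0.0502 ± 0.0437 to 5.42 ± 2.62 CPM. In MHC class II presentation, 6 rose and 9 did not pass, against 9 higher adjusted over the list alone (adjusted p = 4.3e-11, and 0.0211 with an estimated correlation). H2-Aa rose from 64.9 ± 19.8 to 1497 ± 354 CPM. In cytokines and chemokines, 11 rose and 17 did not pass, against 13 higher adjusted over the list alone (adjusted p = 1.6e-09, and 0.0423 with an estimated correlation). Ccl5 rose 10.6-fold. In matrix remodelling, 8 rose and 19 did not pass, against 11 higher adjusted over the list alone (adjusted p = 9.2e-07, and 0.0346 with an estimated correlation). In neutrophil markers, 4 rose and 8 did not pass, against 4 higher adjusted over the list alone (adjusted p = 8.9e-06, and 0.0211 with an estimated correlation). Among monocyte-derived macrophage genes, 9 rose and 15 did not pass, against 12 higher adjusted over the list alone (adjusted p = 1.8e-08, and 0.0425 with an estimated correlation). The list's median log2 fold change was 1.43, or 1.11 with a floor of 3 counts in each library for groups at 0 counts. Dendritic cell markers (adjusted p = 7.3e-06, and 0.0425 with an estimated correlation) rose in 6 of 14 members, and B and plasma cell markers (adjusted p = 0.00266, and 0.0423 with an estimated correlation) in 3 of 10.

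The remaining lists passed at the preset correlation alone. In lipid-associated macrophage genes, 9 rose and 11 did not pass, against 15 higher adjusted over the list alone (adjusted p = 2.3e-11, and 0.0521 with an estimated correlation). Cd63 rose from 104 ± 43.5 to 1081 ± 552 CPM. In interferon response, 8 rose and 33 did not pass, against 13 higher adjusted over the list alone (adjusted p = 4.7e-06, and 0.0696 with an estimated correlation). Oxidative phosphorylation (adjusted p = 7.1e-04, and 0.351 with an estimated correlation), antioxidant enzymes (adjusted p = 0.00101, and 0.108 with an estimated correlation), NRF2 targets (adjusted p = 0.00654, and 0.25 with an estimated correlation) and lysosome genes (adjusted p = 0.0284, and 0.413 with an estimated correlation) were higher, and cell cycle genes (adjusted p = 0.00106, and 0.413 with an estimated correlation) lower. Erythroid markers did not pass in knockout cells (adjusted p = 0.859). Lists that did not pass (adjusted p = 0.173 to 0.859) held genes past the threshold, higher and lower: lipid uptake and storage (3 and 1), cholesterol efflux (5 and 0), NF-kappaB targets (3 and 0), apoptotic cell clearance (3 and 3) and pattern recognition (3 and 0).

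The wild-type count was 1123 with only the 2 groups in the fit, 3968 by voom, 1502 without 12-week replicate 2, and 1193, 1422 and 1069 without 4-week replicates 1, 2 and 3. Without 4-week replicate 2 the log2 fold changes were -1.72 for Car2, -2.60 for Tent5c, -2.27 for Alas2, -4.55 for Slc4a1, -2.13 for Rsad2, 5.56 for H2-Aa, 4.98 for H2-Eb1, 4.87 for Cd74 and 4.91 for H2-Ab1, each moving the fold by more than 1.5 times. So did leaving out 12-week replicate 1 (Hr 3.00, Tent5c -4.42, Rsad2 -4.45, Fth1 -3.66), replicate 2 (Slc4a1 -7.18) and replicate 3 (Bhlhe41 -3.08). H2-Ab1 missed the threshold without any 1 of 3 of the 6 libraries, and Cybb without any 1 of 2. Car2 and Rsad2 missed the threshold by voom, and 5 of 11 list calls held without any single library. The knockout count was 1646 with only the 2 groups, 1679 by DESeq2 (1698 on the genes kept here), 2640 by voom, 359 and 377 without 12-week replicates 1 and 3, and 329, 280 and 235 without 4-week replicates 1, 2 and 3. Folds moved by more than 1.5 times (log2 given) without 12-week replicate 1 (Pla2g2d 5.12) or replicate 2 (Pdcd1 8.51, Cd3e 5.53), and without 4-week replicate 1 (Cd3e 7.40), replicate 2 (Pla2g2d 7.77) or replicate 3 (Pla2g2d 6.12). Itgam and Rem1 missed the threshold without any 1 of 4 of the 6 libraries (Itgam at log2 1.29 to 1.81), and Fth1 without any 1 of 3.

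**Figure D4:**
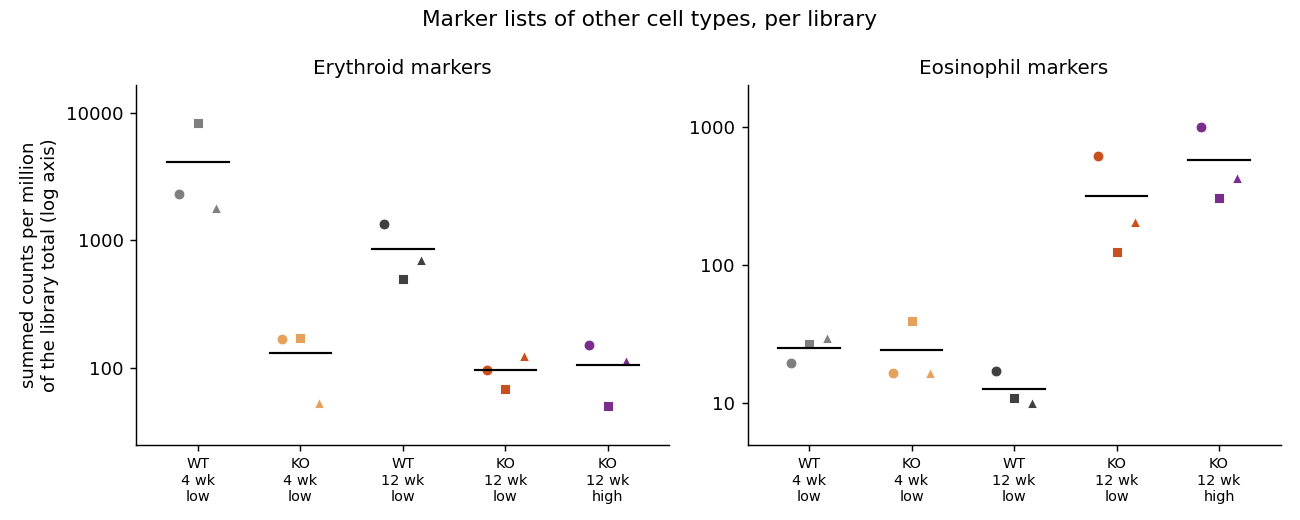
Summed CPM of the 7 erythroid genes and of the eosinophil markers (nearly all Ear6 in CD11b-low groups), per library total, on a log axis for every library by group, with circle, square and triangle for replicates 1, 2 and 3 and a black line at the mean. Erythroid genes sum to 1812 to 8333 CPM in 4-week wild-type libraries and to at most 171 CPM in any knockout library.

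Libraries differed in ways the groups do not name. Wild-type 12-week replicate 1 had the highest share of antisense (0.532%), lincRNA (1.19%) and miRNA (0.648%) counts and the lowest library weight in voom (0.124). The 12-week groups spread more than the 4-week ones, with a median SD of log2 CPM of 0.526 in wild-type, 0.389 in CD11b-low and 0.367 in CD11b-high knockout cells, against 0.259 and 0.189 in wild-type and knockout cells at 4 weeks. Fth1, which fell with age in both genotypes, parted CD11b-high replicates 2 and 3 from replicate 1. H2-Ab1 was lowest in replicate 1 of each 12-week group.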

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

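Chosen after the results were seen were the test of a lower macrophage share, the sum of T and NK markers without Cd2, the condition under which the red blood cell test counts as void, and, for Fth1, its own shared sequence, the spread of positions and the counts of genes by replicate.

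The genotype effects at 4 and 12 weeks differed, by an interaction test, in 33 genes and 18 gene lists. None of the lists passed with an estimated correlation between genes, and 9 did by fry. The differences between the effects, on the log2 scale, were 7.55 for Cxcr6, 5.36 for Cd3g, 4.84 for Ear6, 4.82 for Tent5c, 4.63 for Fstl1, 4.57 for Mfge8, 4.25 for Lck and 3.51 for Mmp12. Of 100 regroupings drawn from 200 possible within each age, 10 gave at least 33 genes, the real one included, and the highest other gave 105, so chance cannot be excluded for the count. All 10 left the 12-week libraries in their genotype groups, as 12 of the drawn did, and the highest count with the 12-week libraries regrouped was 0. The regrouping with 105 held the real groups with the genotypes of 1 age swapped, so it adds the genotype effects of both ages, and those that kept the 12-week groups alone reached 77 at most. Such counts follow the 12-week groups and test neither the interaction nor a cause.

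For each other comparison the 6 libraries make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes. The real count and the highest other were 412 and 0 for knockout against wild-type cells at 12 weeks, 13 and 1 at 4 weeks, 1970 and 2 for CD11b-high knockout against wild-type cells, 915 and 0 with age in knockout cells and 2282 and 0 in wild-type cells. For CD11b-high against CD11b-low knockout cells they were 92 and 87. The split with 87 set CD11b-high replicate 1 and CD11b-low replicates 1 and 3 against the rest and parts only 1 of the 3 replicate pairs. Among the 4 splits that part all pairs, as the real one does, the highest other was 0.

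T and NK cell markers were higher as a list in knockout CD11b-low libraries at 12 weeks (adjusted p = 1.8e-15, but 0.0527 with an estimated correlation and 0.00254 by fry). Their summed CPM was not, since Cd2 made most of it. Without Cd2 the sums were 51.9 to 149.9 and, in wild-type libraries, 3.88 to 9.49 CPM. If RNA of such cells were in the sorted samples, T cell genes outside the list would rise too, and the 21 tested of 25 had a median log2 fold change of 3.48 (MAD 1.21), with 20 above 0, 7 of them past the threshold, and -0.17 at 4 weeks. The most abundant were Cd247 (9.84 against 0.18 CPM), Icos (7.51 CPM) and Gimap4 (5.96 CPM), and 19 stood under 1 CPM in wild-type libraries. A lower macrophage share would raise markers of every other cell type. Erythroid and lung epithelial medians were -2.91 and -1.29 beside 3.56 for T and NK markers, but both lists were lower at 4 weeks too. Neutrophil, dendritic and B cell lists rose, so a lower share stays open. T or NK cell RNA may be a source, although the sort should remove such cells, and expression in the macrophages stays open and untested.

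Erythroid genes were lower in knockout libraries at 4 weeks. If red blood cell RNA in the wild-type samples were the source, red cell genes outside the list would be lower too. The 16 tested of 28 had a median log2 fold change of -0.16 (MAD 0.486), above the bound of -0.25 set beforehand, by less than that spread, and 11 of the 16 had a value below 0. After this value was seen the test was judged void, because 7 of the 16 stand at 10 CPM or more in 4-week knockout cells, such as Hebp1 (439 against 489 CPM), and 5 stand under 1 CPM in both, so a small share of red cell RNA would not show in them. Red cell RNA as a source and lower expression in the sorted cells cannot be told apart here.

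Fth1 was lower at 12 weeks except in CD11b-high replicates 2 and 3, where it stood 3.32 higher on the log2 scale than in replicate 1. Reads shared with near-identical copies would need much shared sequence, and Fth1 shares 2.88% of its 50-mers. This argues against exact copies only. The 486 genes sharing at least 50% differed by -0.0123 from 12788 others, within their spread (MAD 0.555). A library batch shared with the 4-week libraries would place replicates 2 and 3 near the 4-week level for genes that change with age, and 389 such genes had a median position of 0.804 and 0.822, on a scale from 0 at 4 weeks to 1 at 12 weeks (1.21 in replicate 1). These lie above the bound of 0.5 set beforehand, by less than the genes' spread (MAD 0.384 and 0.47), and other genes went with Fth1. Of the 389, 60 lay under 0.5 in both replicates 2 and 3 and not in replicate 1, against 2 and 1 with replicate 2 or 3 as the odd one. Among them, named after their values were seen, Atp5d stood at 82.4 and 118 CPM in replicates 2 and 3 and 18.2 CPM in replicate 1, and Map4k1 at 19.6 and 21.5 CPM and 2.12 CPM. A library batch and inexact copies stay open, and no biological explanation was tested, since no group parts these replicates.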

How the results depend on the processing

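DESeq2 on the genes kept by the filter was added after the results were seen. No value of 6841 compared reversed its direction among called results. RLE size factors left every count of genes within 1.5 times, and the Cybb differences at -2.66 and -3.15. The median log2 fold change of all genes was -0.04 to 0.01. Depth limits genes near the filter, and changes of 2-fold were recovered in 4 to 20% of simulated genes. The cause of the shifts was not tested, and fits without libraries or groups held fewer samples.

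Without a filter on low counts, genes called numbered 1090 for knockout against wild-type cells at 12 weeks, 73 at 4 weeks, 533 for CD11b-high against CD11b-low knockout cells, 1395 with age in knockout cells and 321 in the interaction. By DESeq2 on all genes with its own filter these were 864, 22, 274, 1679 and 151, and the overlaps were 12 genes between the ages and 756 between the knockout subsets. By DESeq2 on the genes kept by the filter they were 880, 24, 261, 1698 and 151, and 12 and 768. By limma voom with library weights they were 165 for CD11b-high against CD11b-low cells, 2640 with age in knockout and 3968 in wild-type cells. With only the groups compared in the fit they were 189 and 4 for knockout against wild-type cells at 12 and 4 weeks, 18 for CD11b-high against CD11b-low cells, 793 for CD11b-high knockout against wild-type cells, and 1646 and 1123 with age in knockout and wild-type cells.

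The replicate number as a block moved the interaction count to 66 genes, 32 of them shared, although pairing is unclear there. It left other counts within 1.5 times, with 97 genes for CD11b-high against CD11b-low cells, whose pairs alone were not fitted.

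With an estimated correlation, lists called numbered 0, 4, 7, 9, 8, 0 and 0, in the order knockout against wild-type cells at 12 weeks, at 4 weeks, CD11b-high against CD11b-low cells, CD11b-high knockout against wild-type cells, age in knockout cells, age in wild-type cells and interaction. By camera at the preset correlation they were 21, 10, 17, 17, 15, 11 and 18. By fry 2 were called at 4 weeks, 7 with age in wild-type cells and 9 in the interaction.

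Leaving out 1 library gave 230 to 426 genes for knockout against wild-type cells at 12 weeks, the lower counts being 230, 257 and 271 without knockout replicate 2, wild-type replicate 1 and wild-type replicate 2. At 4 weeks it gave 4 to 15, with 7, 4 and 7 without knockout replicates 1, 2 and 3. For CD11b-high against CD11b-low cells it gave 2 to 247, with 247, 20 and 21 without CD11b-high replicates 1, 2 and 3, and 3 and 2 without CD11b-low replicates 2 and 3. For CD11b-high knockout against wild-type cells it gave 952 to 2099, with 952 without CD11b-high replicate 2. With age in knockout cells it gave 235 to 1305, with 359 and 377 without 12-week replicates 1 and 3 and 329, 280 and 235 without 4-week replicates 1, 2 and 3. With age in wild-type cells it gave 1069 to 2528, with 1502 without 12-week replicate 2 and 1193, 1422 and 1069 without 4-week replicates 1, 2 and 3. The interaction gave 3 to 35, with 3 without 4-week knockout replicate 3, 13 without 4-week wild-type replicate 2, and 21 without 12-week knockout replicate 1, without wild-type replicate 1 and without wild-type replicate 3.

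Lists called without 1 library numbered 17 to 20 for knockout against wild-type cells at 12 weeks, 5 to 13 at 4 weeks (5 without knockout replicate 2, 6 without wild-type replicate 3), 15 to 18 for CD11b-high against CD11b-low cells and 17 to 22 for CD11b-high knockout against wild-type cells. They numbered 14 to 15 with age in knockout cells, 6 to 11 in wild-type cells (6 without 12-week replicate 2) and 16 to 20 in the interaction. Of the genes with the largest changes, those past the threshold in every left-out library were 12 of 20, 3 of 10, 2 of 20, 7 of 10, 7 of 10, 8 of 10 and 2 of 5, in the order of comparisons used for the lists above.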

Other observations

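Sex-linked genes, in CPM of the library total, differed between libraries of one group. Xist stood at 10.7 to 26.2 CPM in replicates 1 and 3 of both 12-week knockout subsets, and at 0.0295 and 0.175 CPM in replicate 2 of the CD11b-low and CD11b-high cells. The same libraries held the Y-linked Eif2s3y at 39.5 to 123 CPM. In 12-week wild-type libraries Xist was at most 0.0853 CPM, with Eif2s3y at 57.5 to 104 CPM. At 4 weeks Xist stood at 14.96 CPM in knockout replicate 1, and at 15.5 and 36.2 CPM in wild-type replicates 1 and 3. In wild-type replicate 3 Eif2s3y was 0.928 CPM and Ddx3y 0.398 CPM. Xist therefore went with genotype in part at 12 weeks, and the sexes of the mice were not among the labels.

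Ear6, of the eosinophil list, rose from 13.2 to 349.9 CPM in 12-week knockout against wild-type cells, while Siglecf, which eosinophils also carry, stood at 240.2 and 276 CPM. Bhlhe41, a gene of alveolar macrophage identity, stood at 423 CPM in CD11b-low knockout and 79.1 CPM in wild-type cells at 12 weeks, and at 444 CPM in wild-type cells at 4 weeks. Evx2 had 0 counts in all 6 wild-type libraries and 9 to 33 in the 9 knockout libraries, and Dscaml1 had 0 to 2 and 37 to 79 counts. No explanation of these values was tested.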
